A study of Mus musculus with 72 samples.

How the data were processed

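Whole livers of C57bl6 mice of both sexes, 8 to 16 weeks old and held on a 12:12 h light and dark cycle per the labels, were profiled by poly(A) selected, stranded, paired-end sequencing with reads of 150 bp. Per the submitters' processing notes, reads were aligned with STAR 2.6.0c to the mouse genome GRCm38 and quantified per gene, exon and intron. The deposited files hold read counts per gene, exon or intron in whole numbers, sense and antisense to the gene, each in a version restricted to reads assigned to 1 feature (MIN) and a version that also counts ambiguous reads (MAX). Library totals were nearly equal: the sense gene counts of the restricted version ranged from 11551524 to 12529963, a ratio of 1.085, so totals carry little information on the original depth. All comparisons use the sense gene counts of the restricted version. The MAX version (14059258 to 15112733 counts per library) was an alternative, and the sense intron counts (1000985 to 1016503) and antisense gene counts (23978 to 36995) were looked at separately. Exon counts and the remaining files were not used here. Every column was matched to a sample by sex, treatment, clock time and replicate number, and 0 columns were left over.

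Genes were kept by edgeR's filterByExpr over the 24 groups, which left 15066 of 27846 genes. TMM factors ranged from 0.836 to 1.17. Counts were fitted with edgeR 4.0.16 in R 4.3.3 by a robust quasi-likelihood negative binomial model with 1 mean per group (24 coefficients, 48 residual degrees of freedom). Mean effects of misalignment in each sex, their difference, and the sex difference in controls and in misaligned mice were contrasts averaged over the 6 clock times. Effects by clock time were tested with 5 degrees of freedom, as whether the misalignment effect was equal at all 6 clock times. Rhythms were fitted as a cosine and a sine of 24 h per sex and treatment, tested with 2 degrees of freedom (60 residual), for rhythm within a group, change with misalignment, sex difference of that change, and sex difference in controls. Tests were 2-sided, and p-values were adjusted over the genes of each test by Benjamini and Hochberg with a threshold of 0.05. Log2 CPM used a prior count of 2. Amplitudes run from mean to peak in log2, and an interval of confidence, where given, is at 95%.

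Gene lists, 36 in all with 803 members in the table and 15 absent from it, were fixed before the data were examined, as were the groups, the contrasts, the alternatives and the rule for named genes. Lists with at least 5 tested genes, 34 of the 36, were tested with camera of limma 3.58.1 at a preset correlation of 0.01, again with an estimated correlation, and with fry, which tests whether a list moves on balance in 1 direction. Enrichment of lists among called genes used Fisher's exact test against all tested genes. It treats list members as independent and was not repeated on regrouped samples, so its p-values can be too small where members vary together. Named genes were, for each mean contrast, the 8 called genes with the largest positive and the 8 with the largest negative log2 difference among those with a mean of at least 2 CPM and the same direction at 5 or more clock times. Further named genes were up to 4 members per list with the smallest p, all core clock genes, the 10 with the smallest p per rhythm comparison, the 8 with the largest amplitude per group and the sex chromosome genes. Predicted genes and pseudogenes were left out. Other list members are given as values, and genes outside the rule are said to be so.

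The molecular time of a liver was read from the core clock genes called rhythmic in both control groups, 14 in number. Their log2 CPM, centred on the mean of the control curve, were regressed on the cosine and sine coefficients of the control curve of the same sex, and a control liver was read against a curve fitted without it. Group differences in offset, concentration and amplitude were tested with 100000 permutations. Correlations across livers used 100000 permutations. The model was tested on simulated data with 200 changed genes, and counts were compared with those of 100 random regroupings of the samples within the other factors, the real one included.

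Alternatives were the RLE size factors of DESeq2 1.42.0, total counts, no filter, a filter at a mean of 5 CPM, limma-voom, DESeq2, the older edgeR dispersion estimate, MAX counts, a test across clock times in place of the cosine, a minimum peak-to-trough ratio of 1.5, a block for the replicate number, and leaving out each replicate number, library and clock time. Fits on the compared libraries alone were added after seeing the data. Gene positions are those of GENCODE vM21 on GRCm38, as the intervals in the files were wider by 300 bp on each side for 14342 of 15063 matched genes. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.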

Results

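Gene expression was measured by poly(A) RNA sequencing of whole liver from C57bl6 mice of both sexes on a high-fat diet, with 42% of calories from fat. Mice were kept as controls or under chronic circadian misalignment, a paradigm whose schedule the labels do not describe. Livers were taken at 6 clock times, 0, 4, 8, 12, 16 and 20 h, from 3 mice per sex, treatment and clock time. Clock times are as stated in the labels, which do not say how the clock time of misaligned mice related to their light cycle on the day of collection, so earlier, later, ahead and behind refer to the stated time only. The 72 libraries thus formed 24 groups of 3, or 18 libraries for each sex and treatment. The gene table held 27846 genes, and a library carried 11551524 to 12529963 gene counts, with a median of 12005221. Between 18013 and 19246 genes had at least 1 count in a library, and 15066 genes were tested. At this depth the median standard error of a log2 change between treatments within a sex was 0.10.

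Sex chromosome genes were read first, because every comparison rests on the sex labels. Xist (ENSMUSG00000086503, chromosome X, 103460366 to 103483254), the RNA that silences one X chromosome in female cells, had 2508 to 4573 counts in the 36 female libraries and 0 to 4 in the 36 male libraries. The Y-linked translation factor gene Eif2s3y had 445 to 932 counts in males and 0 to 2 in females, and the helicase gene Ddx3y had 117 to 615 in males and 0 to 1 in females. These genes contradicted the sex label of 0 of the 72 libraries.

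The first question was how liver transcripts cycled over the day in control mice of each sex. Arntl (ENSMUSG00000055116, chromosome 7, 113207465 to 113314126) encodes the activator BMAL1 that drives the core clock. Its fitted 24 h rhythm had an amplitude, taken from mean to peak, of 2.65 ± 0.22 log2 (± SE, n = 18) with a peak at 21.4 ± 0.31 h in control females, and 2.25 ± 0.18 log2 with a peak at 20.4 h in control males. Its partner Npas2 had amplitudes of 3.70 in females and 3.29 in males. Dbp, a clock-driven transcription factor gene, cycled in the opposite phase, with an amplitude of 3.22 and a peak at 9.07 h in females and an amplitude of 3.23 and a peak at 8.20 h in males. Nr1d1, which encodes the repressor REV-ERB alpha, peaked at 6.09 h in females and 5.24 h in males. Per3 peaked at 10.7 and 9.62 h and Ciart at 10.9 and 9.09 h. Per2 peaked at 13.2 h in control females and was not called rhythmic in control males (edgeR adjusted p = 0.0898). By edgeR 1803 genes were called rhythmic in control females and 1625 in control males, and 760 were called in both where 194 would be shared by chance.

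Gene lists beyond the clock also held many rhythmic genes in controls. The core clock list had 15 of 19 members called in control females (Fisher's exact test on the called genes, adjusted p = 5.77e-10) and 14 of 19 in control males (adjusted p = 3.21e-09). Chaperone genes of the heat shock list were called in 13 of 21 cases in control females (adjusted p = 9.01e-07), among them Hspb1 with an amplitude of 0.97 and a peak at 18.3 h, and Hsp90aa1 with a peak at 17.7 h. Interferon response genes were called in 13 of 37 cases in control females (adjusted p = 0.00186), including Psmb8, Igtp and Gbp3. In control males the unfolded protein response list had 17 of 30 members called (adjusted p = 1.15e-08). Hspa5, which encodes the chaperone BiP, had an amplitude of 0.67 ± 0.09 and peaked at 22.3 h, close to Manf at 22.5 h and Hyou1 at 22.3 h. Cell cycle genes were called in 11 of 28 cases in control males (adjusted p = 7.09e-04), with Tk1 peaking at 12.3 h and Cdkn1a at 18.8 h. A list called in one sex alone is not a sex difference: the test of the difference between control rhythms of females and males called 0 genes by edgeR, with 739 at an unadjusted p under 0.05 and a smallest adjusted p of 0.331 for Bnc1, and 0 by limma-voom. Over the 760 genes called in both sexes the median peak was 0.73 h earlier in males.

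**Figure D1:**
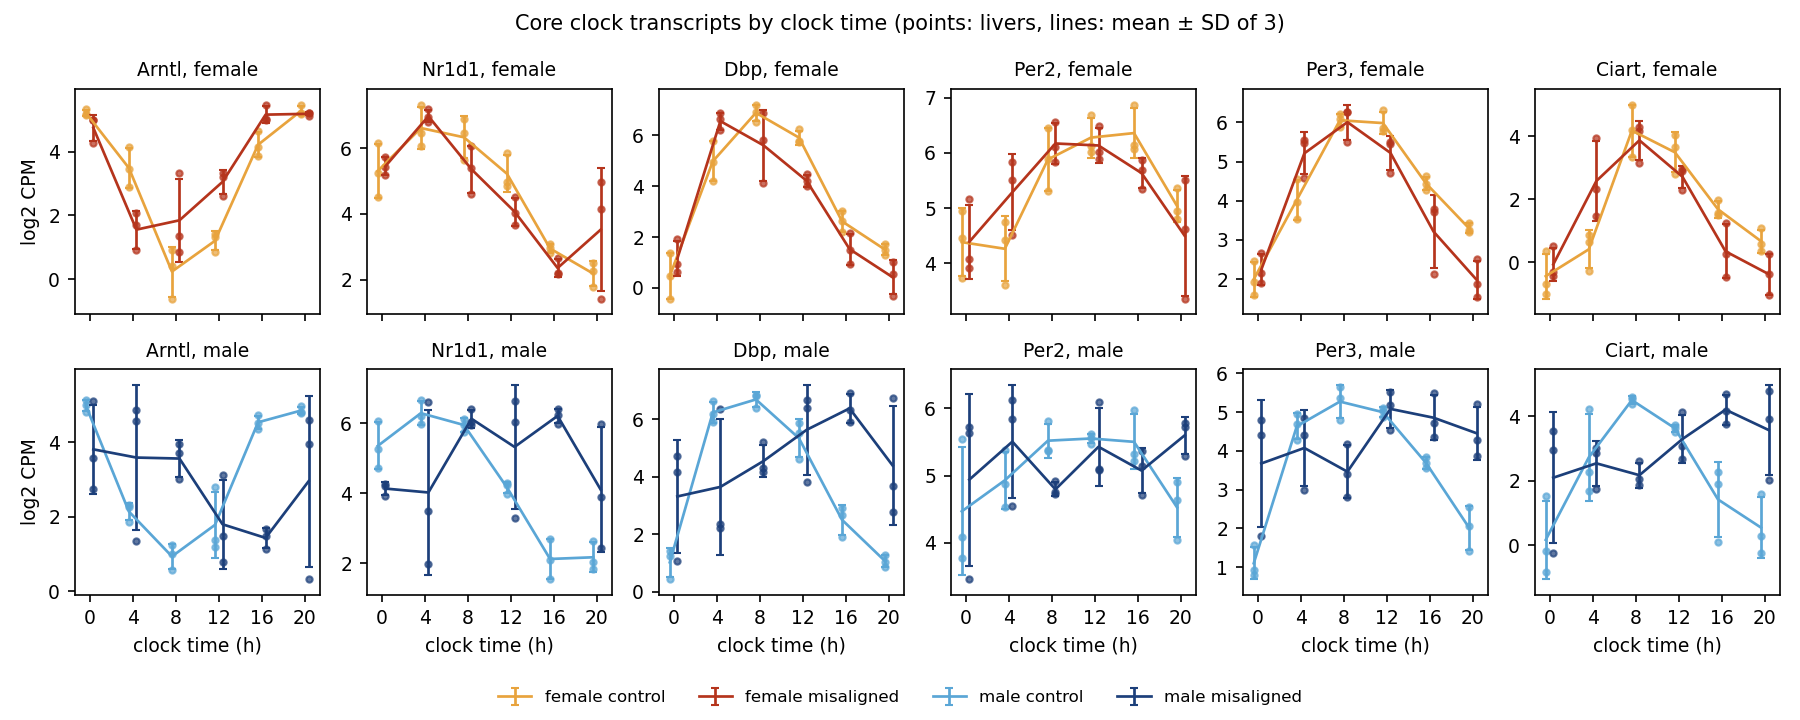
Log2 CPM (gene counts scaled to the library) of 6 core clock transcripts against clock time in hours, females above and males below, with 1 point per liver and lines through the mean of 3 livers, error bars giving their SD. Arntl points of misaligned males lie far apart at 1 clock time, with an SD of 1.43 on average against 0.41 in male controls, while Ciart points differ less, with 1.12 against 0.961.

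In females the question was what misalignment did to these rhythms. Clock genes still cycled in misaligned females and peaked earlier than in control females. Arntl peaked at 19.0 h with an amplitude of 2.07 ± 0.24, Dbp at 7.30 h with an amplitude of 3.13, Nr1d1 at 4.24 h with 2.08 and Per2 at 10.5 h with 1.00. Npas2 moved from 22.3 to 20.3 h and the transcription factor gene Tef from 11.1 to 8.23 h, and both passed the test for a change in rhythm at an adjusted p of 0.022. Arntl itself moved by -2.43 ± 0.54 h and did not pass it (adjusted p = 0.157). The fitted peaks of all 19 core clock genes lay earlier, by a median of 2.43 h, although some, such as Rora, had no called rhythm in females, and 2 passed over all genes tested while 13 did when adjusted over the list alone. Over the 758 genes called rhythmic in both groups of females, 139 of them expected by chance, 94.6% peaked earlier after misalignment, by a median of 2.26 h.

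The smallest p-values for a rhythm change in females belonged to genes outside the clock. Each gene's spread was estimated over all 72 libraries, so the scatter of clock genes in misaligned males also entered the female tests. The median SD of core clock genes within a clock time was 0.734 log2 in misaligned males. In control females it was 0.435 and in misaligned females 0.477, so the ranking depends on this shared estimate. Plekhd1 had the smallest adjusted p, 9.49e-06, with a fitted amplitude of 1.63 ± 0.54 and a peak at 1.65 h in controls, and an amplitude of 0.82 and a peak at 17.3 h after misalignment. Adcy1, an adenylate cyclase gene, went from an amplitude of 2.40 peaking at 23.3 h to 1.39 peaking at 18.7 h, and the synaptic gene Rims4 from 1.51 peaking at 0.37 h to 1.09 peaking at 17.4 h, both at an adjusted p of 0.00709. Hmgcs1, which encodes an early enzyme of cholesterol synthesis, moved from 0.80 to 18.4 h and its amplitude from 0.73 to 0.36 (adjusted p = 0.042). It was 1 of 25 cholesterol synthesis genes to pass over all genes, while 14 did when adjusted over the list alone. By edgeR 1158 genes were called rhythmic in misaligned females and 29 changed rhythm, with 1236 at an unadjusted p under 0.05. The 29 were unstable: leaving out 1 library gave 7 to 56 genes, and leaving out a replicate number gave 1 or 2. A fit of the female libraries alone called 60, with 21 of the 29 among them. Cpt1a and Pdk4, which control fatty acid oxidation, were among 9 of 34 genes of the PPAR alpha list called in misaligned females (Fisher's exact test, adjusted p = 0.00928). The test of each clock time on its own curve, with 5 degrees of freedom, called Plekhd1, Pxdc1, Adcy1, Rims4 and Tmem218.

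In males clock rhythms were fitted flatter and later after misalignment than in controls. The fitted amplitude of Arntl was 1.23 ± 0.44 in misaligned males against 2.25 ± 0.18 in controls, and its peak lay 6.31 ± 1.41 h later (adjusted p = 3.13e-05). Npas2 went from an amplitude of 3.29 to 1.24 and from a peak at 20.9 h to 4.25 h (adjusted p = 6.5e-06), Dbp from 3.23 to 1.46 and from 8.20 to 14.1 h, Nr1d1 from 2.34 to 1.10 and from 5.24 to 12.2 h, and Per3 from 2.07 to 0.67 and from 9.62 to 15.3 h. All 19 core clock genes, those with no called rhythm included, were fitted later and lower, by a median of 6.88 h and a median amplitude difference of -0.52, and 14 passed over all genes tested (17 adjusted over the list alone). The clock outputs Wee1, a mitotic kinase gene, and Nampt, which makes NAD, went from amplitudes of 1.09 to 0.48 (adjusted p = 8.49e-05) and of 0.49 to 0.23 (adjusted p = 1.07e-04). Chka, the choline kinase gene, had an amplitude of 1.89 ± 0.10 peaking at 20.4 h in control males and 0.82 ± 0.31 peaking at 3.33 h in misaligned males (adjusted p = 8.7e-07). Lipe, the hormone-sensitive lipase gene, went from 0.81 peaking at 9.09 h to 0.42 peaking at 18.6 h (adjusted p = 2.04e-06).

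By edgeR 1391 genes changed rhythm in males, with 3634 at an unadjusted p under 0.05, and 1071 of them were among the 1625 genes called rhythmic in control males, an overlap that the shared control libraries raise. Over those 1625 genes, chosen in control males, the fitted amplitude in misaligned males was 0.462 of that in controls (median) and the peak was 7.77 h later. For comparison, misaligned females had 0.679 of the male control amplitude over the same genes. Only Zfp979 was called rhythmic in misaligned males, at an adjusted p of 0.046 and an amplitude of 0.69 ± 0.17. It was chosen after its values were seen, and 1183 genes had an unadjusted p under 0.05. When adjusted over the list alone, 12 of 19 core clock genes and 8 of 19 clock outputs were rhythmic in misaligned males. Beyond the clock, 17 of 30 unfolded protein response genes changed rhythm in males (Fisher's exact test, adjusted p = 9.91e-10). Hspa5 went from 0.67 to 0.20 in amplitude (adjusted p = 2.67e-04) and Manf from 0.82 to 0.28 (adjusted p = 1.46e-04). The test that the misalignment effect was equal at all clock times called 1395 genes in males, of which 840 also changed by the rhythm test on the same libraries. These included 13 of 40 genes of amino acid catabolism (Fisher's exact test, adjusted p = 3.27e-04), among them Asl of the urea cycle and the glycine cleavage gene Gldc.

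A single liver also gives a clock reading, which shows whether a weaker group rhythm came with weaker clocks in the mice. The expression of 14 core clock genes in each liver was matched to the control curve of its sex, which returned a molecular time and an amplitude relative to that curve. This measure was chosen after the clock profiles had been seen. Control livers read close to their clock time, with an SD of the offset of 1.04 h in females (mean -0.03 h, n = 18) and 1.2 h in males (mean -0.03 h, n = 18). A mean near 0 follows from reading control livers against curves of their own group, so the SD is the informative value. Misaligned females read ahead by 2.31 h (SD 1.48, n = 18), with a range of -0.20 to 5.82 h. The shift from control females was 2.32 h (2-sided permutation test, p = 1e-05, the smallest the permutations can give; adjusted over 6 tests, p = 3e-05). Misaligned males read behind, with a circular mean offset of -7.34 h, and 15 of 18 lay more than 4 h from their clock time, against 0 of 18 control males. Their offsets were also scattered, since 5 of 18 lay within 2 h of the group's own mean, against 16 of 18 in control males. Concentration of the offsets, which is 1 when all livers share 1 offset and 0 when they have no common one, was 0.516 in misaligned males against 0.954 in control males (permutation p = 1e-05, adjusted p = 3e-05) and 0.932 in misaligned females (permutation p = 1e-04, adjusted p = 2e-04). The amplitude in a single liver, relative to the control curve, had a mean of 0.951 in misaligned males and 1.01 in control males (permutation p = 0.358, adjusted p = 0.359).

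**Figure D2:**
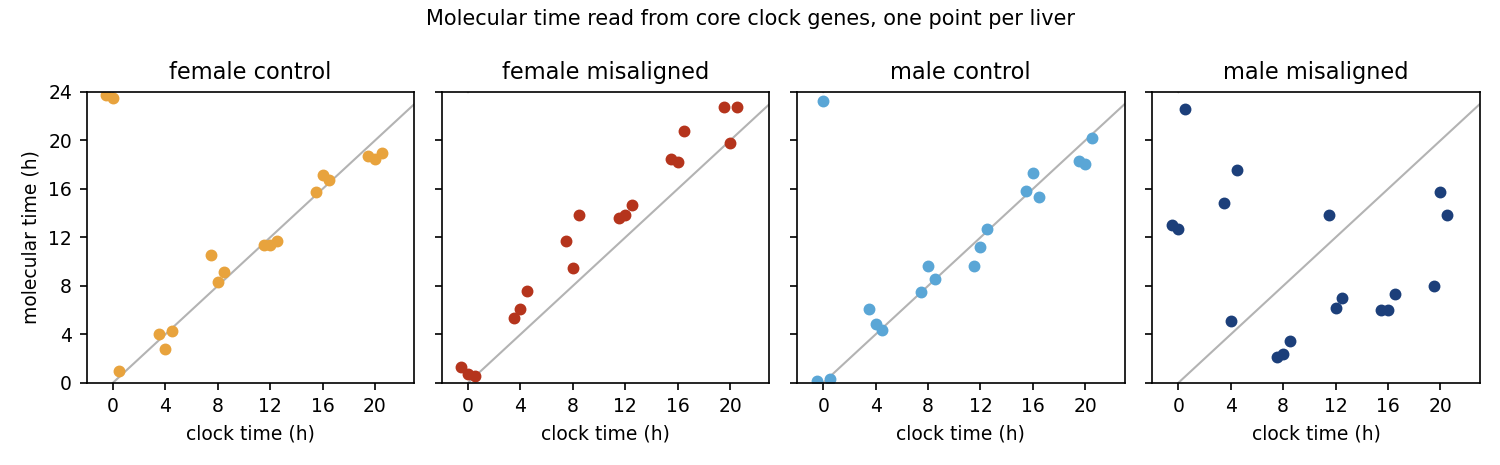
Molecular time in hours, read from 14 core clock genes, against the clock time of collection in hours, with 1 point per liver, 18 per panel, and grey lines where both are equal. Control livers follow the line, misaligned females lie ahead of it by 2.31 h on average, and misaligned males lie behind it, at a mean offset of -7.34 h, and scattered, with 5 of 18 within 2 h of that mean.

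Whether the sexes responded differently was tested as the difference between the rhythm changes. The change in rhythm of Npas2 differed between the sexes (adjusted p = 1.48e-05), as did that of Arntl (adjusted p = 9.75e-04), Chka (adjusted p = 1.48e-05) and the mitochondrial chaperone gene Clpx (adjusted p = 5.18e-05). By edgeR 260 genes differed, with 2126 at an unadjusted p under 0.05, and 238 of them were also called in males, whose change is part of this test. Among them were 14 of 19 core clock genes (Fisher's exact test, adjusted p = 5.36e-20) and 12 of 19 clock outputs (adjusted p = 4.17e-16). The unfolded protein response list gave 7 of 30 (adjusted p = 6.91e-06) and the PPAR alpha list 4 of 34 (adjusted p = 0.0227), namely Acot3, Acot4, Cpt1a and Pdk4. Fisher's exact test takes members as independent, so these p-values can be too small for members that vary together. Of the 29 genes called in females, 17 were also called in males where 3 would be shared by chance.

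Averaged over the clock times, misalignment changed few transcript levels in females. Ppbp (ENSMUSG00000029372, chromosome 5, 90768518 to 90770063), a chemokine gene of platelets, was the only gene called by edgeR, at 3.42 ± 4.66 CPM (gene counts scaled to the effective library size) in control females and 0.462 ± 0.226 in misaligned females (mean ± SD, n = 18). Its log2 change was -2.57 ± 0.44 (± SE, edgeR adjusted p = 0.00547), lower at 6 of 6 clock times, and its mean is below the level set for named genes, so it was chosen after its values were seen. The SD in controls exceeds their mean, and the edgeR call is lost when 1 of 3 control libraries is left out, namely female control 00:00 replicate 2 (adjusted p = 0.0508), 16:00 replicate 1 (adjusted p = 0.194) or 20:00 replicate 3 (adjusted p = 0.331). Ppbp was also not called by limma-voom (adjusted p = 0.357), in a fit of the female libraries alone (adjusted p = 0.302) or without any 1 of the replicate numbers (adjusted p = 0.179 to 0.869). In all limma-voom called 0 genes, with 896 at an unadjusted p under 0.05. DESeq2 called 4, Ppbp among them (adjusted p = 5.61e-07). The edgeR call of Ppbp held with RLE size factors, total counts, no filter, MAX counts, the replicate block and the older dispersion estimate (adjusted p = 8.73e-04 to 0.0184). The erythrocyte membrane gene Slc4a1 (log2 change -2.25, adjusted p = 0.0712) did not pass. All 11 blood cell genes had a negative log2 change, with a median of -1.02, and the list passed (camera adjusted p = 1.12e-19, and adjusted p = 0.0119 with an estimated correlation), with 1 gene lower over all genes and 9 lower adjusted over the list alone. Hbb-bs, a beta globin gene, had 200 ± 131 CPM in control and 109 ± 103 in misaligned females. Males had 74.3 ± 61.9 CPM as controls and 86.8 ± 51.8 when misaligned, so control females were the group with the highest mean. Genes of the unfolded protein response had a positive change in 29 of 30 cases, with a median of only 0.14 log2, and heat shock genes a median of 0.23, but camera called these lists only with its preset correlation (adjusted p = 0.378 and 0.508 with an estimated correlation). The same holds for interferon response genes, with a median of -0.19, and for the acute phase, complement and glucocorticoid lists, each at an adjusted p of 0.935 with an estimated correlation.

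In males 0 genes were called by edgeR for the mean effect of misalignment, with 932 at an unadjusted p under 0.05, against 0 and 823 by limma-voom and 3 and 918 by DESeq2. The smallest adjusted p, 0.201, belonged to Cidea, a lipid droplet gene, at 56.0 ± 28.2 CPM in control and 96.8 ± 48.9 in misaligned males (mean ± SD, n = 18; log2 change 0.80 ± 0.18, positive at 6 of 6 clock times), and to Fbf1 (0.78 ± 0.17). Dbp had a mean log2 change of 1.43 and Per3 of 0.81 (each adjusted p = 0.212) but neither passed. The mean of Dbp over the day was 39.1 CPM in control and 44.5 CPM in misaligned males, as a mean of log2 values gives more weight to the clock times with low expression. Camera with its preset correlation called 18 of 34 lists in males, and with an estimated correlation 0, so these are directions only. Cholesterol synthesis genes were positive in 25 of 25 cases (median 0.28, adjusted p = 0.331 with an estimated correlation) and fatty acid synthesis genes in 22 of 23 (median 0.28, adjusted p = 0.527). Fibrosis genes were positive in 0 of 29 cases (median -0.30, adjusted p = 0.668) and neutrophil genes in 0 of 9 (median -0.82, adjusted p = 0.331). No gene differed between the sexes in its mean response by edgeR: 0 were called with 859 at an unadjusted p under 0.05, against 0 and 762 by limma-voom and 1 and 875 by DESeq2. Blood cell genes were the 1 list whose mean response differed between the sexes with an estimated correlation (adjusted p = 0.0424), out of 15 called with the preset one. On simulated data the same test found 70.1% of genes with a 1.5-fold mean change in females and 100% of those with a 2-fold change. All simulated genes shared 1 dispersion, livers varied independently and the genes with the lowest expression were left unchanged. In the real data 0.339% of genes in females and 0.252% in males had a fitted change beyond 2-fold, with 1 and 0 genes called. The simulation thus does not show that real 2-fold changes would be found.

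In control livers 4964 genes differed between the sexes, 2405 higher in females and 2559 higher in males (edgeR). Female livers expressed sulfotransferases and cytochromes that males nearly lacked. Sult2a2, a hydroxysteroid sulfotransferase gene, had 441 ± 125 CPM in control females and 0.0900 in control males (n = 18 each), Sult2a1 had 402 ± 187 against 0.0315, and Cyp3a41a had 272 ± 93.7 against 0.0180. Sult2a3 was at least 9029-fold higher in females, from a floor of 3 counts over the 18 male libraries, and Cyp3a16 gave a count ratio of 10179 with a 95% counting interval of 2818 to 84056. Cyp2c69 (log2 difference 9.45) and Cux2 (6.65), a repressor of male-biased genes, were also higher. Intervals and floors cover counting error only.

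Male livers were marked by the lauric acid hydroxylase gene Cyp4a12a, at 200 ± 62.8 CPM against 0.204 in control females, and by major urinary protein genes, with Mup20 at 3769 against 30.3 CPM. Genes of lipid storage were also higher in males: Cidea had 56.0 against 0.159 CPM (log2 difference -8.47 ± 0.33, female minus male) and Cidec a log2 difference of -3.69. The fatty acid elongase gene Elovl3 had 226 against 12.1 CPM. Of the lists, female-biased liver genes were higher in 35 of 37 cases (median 5.63, camera adjusted p = 1.81e-09 with an estimated correlation), male-biased genes lower in females in 37 of 44 and higher in 3 (median -2.33, adjusted p = 0.01), and growth hormone and STAT5 target genes higher in 10 and lower in 1 of 16 (adjusted p = 0.0055). These 3 of 18 calls held with an estimated correlation. Others did not, although many members passed one by one: lipid droplet genes were lower in females in 17 of 20 cases (list adjusted p = 0.0735 with an estimated correlation), fibrosis genes in 23 of 29, with Col3a1 at a log2 difference of -1.39, and cell cycle genes in 19 of 28, while interferon genes were higher in 18 of 37, cholesterol synthesis genes in 13 of 25 and Kupffer cell genes in 8 of 14 (adjusted p = 0.515 to 0.616).

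Misaligned mice showed the same division. Of the 5679 genes that differed between misaligned females and males, 2680 were higher in females and 2999 in males, and 3781 were among the 4964 of controls where 1871 would be shared by chance, with 3780 in the same direction. Sult2a1 had 390 ± 153 CPM in misaligned females and 0.0195 in misaligned males, Cyp4a12a 0.263 against 305 ± 144, and Cidea 0.0936 against 96.8 ± 48.9. Of 16 lists called, 4 held with an estimated correlation: female-biased genes (adjusted p = 2.17e-08), male-biased genes, lower in females in 39 of 44 cases (adjusted p = 0.0149), growth hormone and STAT5 targets (adjusted p = 0.0105) and lipid droplet genes, lower in 16 of 20 (adjusted p = 0.0463).

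Male livers also differed from one mouse to the next along the same sex-biased genes. The mean of the male-biased list ran from 4.08 to 6.99 log2 CPM over the 36 males, and Mup7 from 0.308 to 1645 CPM. Livers with high male-biased expression had low expression of macrophage and inflammation genes (Pearson r = -0.80 over 36 males, permutation p = 1e-05, the smallest the permutations can give, adjusted over 36 relations p = 7.2e-05; Spearman rho = -0.78). The relation was -0.77 without the 2 males farthest from the median, -0.81 in control males and -0.92 in misaligned males. Fibrosis genes followed the same pattern (r = -0.74), as did stellate cell markers (r = -0.80) and female-biased genes (r = -0.68). For female-biased genes the relation was weaker in control males (r = -0.55, and -0.32 without the 2 farthest livers) than in misaligned males (r = -0.79). The mean of the male-biased list was 5.34 ± 0.76 in control and 5.58 ± 0.92 in misaligned males (SD, n = 18), a difference below the spread between mice.

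**Figure D3:**
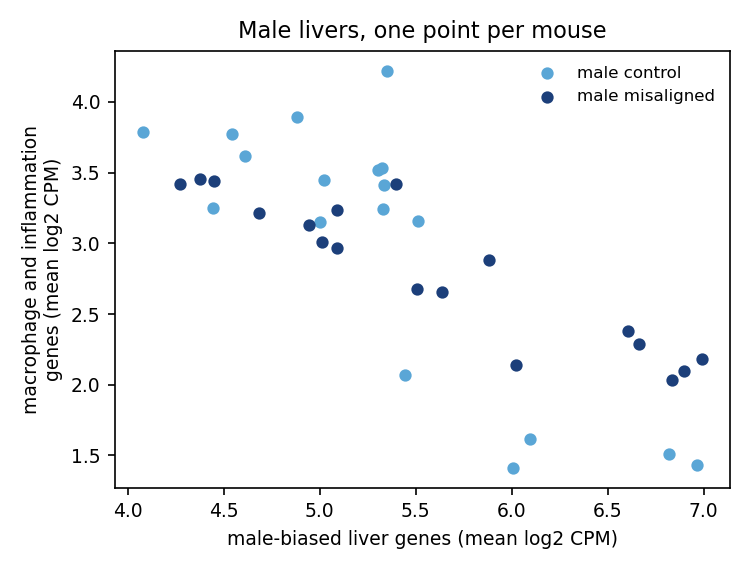
Mean log2 CPM of macrophage and inflammation genes against mean log2 CPM of male-biased liver genes, with 1 point per male liver, 18 control and 18 misaligned. Inflammation genes are lower where male-biased genes are higher, with r = -0.80 over the 36 males.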

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

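Of the tests below, those on noise between libraries, phases of single mice, residual blood, Xist and the share of hepatocytes were chosen only after the results had been seen, and the bounds of the noise and Xist tests were also changed after their values were known, since as first written they gave no decision. The tests on exchanged samples and clock times, the removal of single libraries for Ppbp and all regroupings were set before.

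The rhythm of 260 genes changed with misalignment differently in females and males, which stood out because the difference itself passed the test. Core clock genes made up 14 of them, including Npas2, Arntl and Dbp. When treatment labels were permuted, 1 of 100 regroupings, the real one, gave as many as 260 genes and the highest other gave 75, so chance rarely gives such a count. The same regroupings gave as many rhythm changes as observed in 2 of 100 cases in males (1391 observed, highest other 2002) and 2 of 100 in females (29 observed, highest other 46). Such counts were rare, but a regrouping exceeded each of them, and the shares are not adjusted over the regrouping tests, so chance is not excluded for either.

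Clock genes of misaligned males were spread widely around their common offset: 5 of 18 livers read a molecular time within 2 h of the group's mean offset of -7.34 h, against 16 of 18 in male controls. That measure mixes spread within and between clock times. Offsets ran from -5.87 to -4.51 h at 08:00 and from -10.01 to -8.68 h at 16:00, so the 3 mice agreed there. They lay further apart at the other clock times. At 00:00, 04:00 and 12:00 a single liver read within 2 h of its clock time, with -1.41, 1.08 and 1.88 h. The other livers there lay closer together: -10.96 and -11.3 h at 00:00, and -5.83 and -4.98 h at 12:00. At 04:00 they read 10.86 and -10.4 h, which are near each other on a 24 h circle. At 20:00 the offsets were -11.98, -4.29 and -6.16 h. The tables argue against noisier libraries: over all genes the SD within a clock time was 1.04 times that of male controls, while over the core clock genes it was 1.49 times, above all of 10000 random lists matched on expression. An exchange with male controls would leave control livers out of place, and 0 of 18 read more than 4 h from their clock time. Clock times exchanged within the group left a mean error of 1.85 h after the best reassignment, against 0.929 h in male controls. Random phases gave a median of 1.35 h, so the molecular times were less evenly spaced than a typical random draw. The reassignment assumes 1 common offset, so it cannot exclude that some clock times were exchanged among livers whose offsets differed. A candidate explanation for the spread within a clock time is that single mice kept an ongoing clock at different phases, since the median amplitude in single livers was 0.961 of the control curve. The cause of the differences in offset between clock times was not tested. How the misalignment schedule set the phase of each mouse was not tested. A wrong label from outside the group remains open for single libraries, such as those that read near their clock time.

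Blood cell transcripts were lower in misaligned than in control females, and 15 lists in all had a mean response that differed between the sexes with camera's preset correlation, of which blood cell genes alone, at an adjusted p of 0.0424, did so with an estimated correlation. Control females stood apart from both male groups too for most members. Ppbp had 3.42 CPM in control females, 0.462 in misaligned females, 0.421 in control males and 0.436 in misaligned males. Alas2, Bpgm and Pf4 were not higher in control females than in control males. Less blood left after perfusion in misaligned females could explain their lower values: the 4 globin genes changed by a median of -1.01 log2 and the 7 other members by -1.21, as a common source would give. Ppbp, the 1 called gene, rests on few control livers, since its adjusted p, 4.05e-04 to 0.331 over the 72 fits without 1 library, was 0.331 without female control 20:00 replicate 3, 0.194 without 16:00 replicate 1 and 0.0508 without 00:00 replicate 2. An altered number or state of blood cells in the mice was not tested. Chance cannot be excluded for the count in females, as 12 of 100 regroupings called at least 1 gene and the highest other called 4.

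Male livers differed between individuals along male-biased and inflammation genes. Female RNA mixed into male libraries is excluded as the cause, since the highest Xist count in a male library was 0.122% of the female median. A lower share of hepatocytes would raise markers of every other cell type, but these moved apart: correlations with the male-biased mean were 0.0360 for sinusoidal endothelial and -0.18 for Kupffer cell markers (-0.46 in male controls), against -0.80 for macrophage genes, -0.80 for stellate and -0.63 for cholangiocyte markers, so a rise in those cell types alone stays open. Males may thus have differed in the state of the liver, for instance in growth hormone signalling or in the response to the diet, neither of which was tested against it here.

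Signals also appeared in counts that the comparisons did not use. Intron reads, which follow unspliced RNA, changed rhythm in males for 238 of 12250 genes, 158 of which were also called from gene counts, and for 0 genes in females (edgeR, 807 at an unadjusted p under 0.05). Antisense reads changed rhythm in males for 8 of 656 genes and in females for 0 (54 at an unadjusted p under 0.05).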

How the results depend on the processing

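The fits on the compared libraries alone were chosen after seeing the data, and the other alternatives before. Of 174 counts under alternatives that kept all libraries, 134 stayed within 1.5-fold of those reported, and of 1335 values for 107 named gene results 1258 passed in the same direction, 77 did not pass and 0 reversed. The 40 other counts follow, and unless fewer genes or libraries explain it the cause was not tested. For the misalignment effect in females, 1 gene: 0 with the stricter filter, with limma-voom and with own libraries only, and 4 with DESeq2. For the misalignment effect in males and its sex difference, 0 genes each: 3 and 1 with DESeq2. For the misalignment effect by time in females, 5 genes: 8 with total counts, 3 with no filter, 2 with the stricter filter, 3 with the older dispersion estimate and 23 with own libraries, 1 of them shared. For the misalignment effect by time in males, 1395 genes: 830 with no filter and 387 with own libraries. Of rhythmic genes in female controls, 1803: 1031 with the test across clock times and 1189 with a peak-to-trough ratio of at least 1.5. Of rhythmic genes in female misaligned mice, 1158: 548 across clock times. Of rhythmic genes in male controls, 1625: 847 with own libraries and 1042 with the minimum ratio. Of rhythmic genes in male misaligned mice, 1: 0 with no filter, the stricter filter, limma-voom, the older estimate, MAX counts and own libraries, and 11 across clock times. Rhythm change with misalignment in females, 29: 19 with MAX counts, 5 across clock times and 60 with own libraries, 21 of them shared. Rhythm change with misalignment in males, 1391: 750 with own libraries, 734 of them shared. Sex difference in the rhythm change, 260: 155 with no filter and 130 across clock times. Sex difference in rhythm of controls, 0: 1 with no filter. Lists called with an estimated correlation and with fry were 1 and 1 in females (7 with the preset one), 0 and 0 in males (18) and 1 and 1 for the sex difference of the effect (15). For the sex difference they were 3 and 16 in controls (18) and 4 and 13 in misaligned mice (16). With total counts 42.4% of called genes were higher in females in controls against 48.4% with TMM, and the balance turned in misaligned mice, with 50.8% against 47.2%.

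Leaving out libraries, replicate numbers or clock times gave these lowest and highest counts: mean effect in females 0 to 4, in males 0 to 26, and their sex difference 0 to 4. Sex difference 3331 to 5113 in controls and 3640 to 5806 in misaligned mice. By clock time 0 to 16 in females and 140 to 1942 in males. Rhythmic genes 802 to 1915 in female controls, 402 to 1240 in misaligned females, 387 to 1724 in male controls and 0 to 44 in misaligned males. Rhythm change 1 to 56 in females and 136 to 2040 in males, its sex difference 15 to 423, and control rhythms 0 to 0. Without replicate 1, 134 of the 136 genes with a rhythm change in males were among the 1391, without replicate 2 405 of 442, and without replicate 3 906 of 1373. These single libraries moved a count over 1.5-fold. Ppbp was not called, and the count was 0, without female control 00:00 replicate 2, 16:00 replicate 1 or 20:00 replicate 3. It was 2 without female control 08:00 replicate 1 or female misaligned 00:00 replicate 2, 04:00 replicate 1 or 20:00 replicate 2, and 3 without female control 00:00 replicate 3, 04:00 replicates 1 or 2, 08:00 replicate 2, 16:00 replicates 2 or 3, 20:00 replicate 1, or female misaligned 04:00 replicate 3 or 16:00 replicate 1. The mean effect in males gave 7 genes without male misaligned 00:00 replicate 3 and 1 without 04:00 replicate 1 or 12:00 replicate 1. By clock time in females the count was 16 without male misaligned 00:00 replicate 3, 8 without 12:00 replicate 1, 15 without female control 16:00 replicate 3, 9 without female control 12:00 replicate 3 or female misaligned 04:00 replicate 2 or 20:00 replicate 2, 3 without female control 00:00 replicate 2 or 20:00 replicate 1 or female misaligned 00:00 replicate 2, and 2 without female misaligned 04:00 replicate 3. By clock time in males it was 739 without male control 20:00 replicate 2 and 860 without male misaligned 20:00 replicate 3. Rhythm change in females was 12, 16, 19, 56, 17 and 18 without female control 04:00 replicates 2 and 3, 12:00 replicates 2 and 3, and 16:00 replicates 1 and 2, and 18, 54, 7, 18, 19 and 10 without female misaligned 00:00 replicate 2, 04:00 replicates 2 and 3, 12:00 replicate 3, and 16:00 replicates 1 and 2, and 44 without male control 16:00 replicate 2. The sex difference of the change was 423 without male misaligned 00:00 replicate 3. The 1 rhythmic gene of misaligned males moved with 54 libraries: male misaligned 04:00 replicate 2 gave 43, 12:00 replicate 1 gave 31, 00:00 replicate 3 gave 24, 08:00 replicate 2 gave 7, 00:00 replicate 2 gave 4, 20:00 replicate 2 gave 2, and the other 48 gave 0.

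A replicate block was tried although the numbers paired no libraries: deviations from the group mean of libraries with the same number had a mean correlation of -0.00463, against 0.00250 for other numbers. With the block 1374 genes changed rhythm in males, 26 in females, and 260 differed between the sexes.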

Other observations

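The regroupings were planned and the within-group measures of the male livers were chosen after the values had been seen. With sex labels permuted, only the real grouping reached the count for the sex difference in controls (1 of 100 regroupings with as many genes, 4964 observed, highest other 980) and in misaligned mice (1 of 100, 5679 observed, highest other 28). With clock times permuted, the same held for rhythms in female controls (1 of 100, 1803 observed, highest other 151) and misaligned females (1 of 100, 1158 observed, highest other 29). It also held in male controls (1 of 100, 1625 observed), where the highest other, 1527, came close, but not in misaligned males (25 of 100, 1 observed, highest other 255). Permuting treatment rarely gave as many genes for the effect by clock time in males (2 of 100, 1395 observed), but the highest other was 3033, so chance is not excluded. Counts as high were more common for the effect by clock time in females (12 of 100, 5 observed, highest other 13). They came from every regrouping for the mean effect in males (100 of 100, 0 observed, highest other 1641) and the sex difference of that effect (100 of 100, 0 observed, highest other 101). The same was true, with sex permuted, for the sex difference in control rhythms (100 of 100, 0 observed, highest other 611). Chance is not excluded for any of these. Lists gave the same reading: 88 of 100 regroupings called as many as the 7 lists of females (highest other 20, median 11) and 15 of 100 as many as the 18 of males (highest other 23, median 11), so camera's preset correlation calls lists in these livers without a treatment difference. Regroupings that called 1641 genes for the mean effect in males and 255 for rhythm in misaligned males, many times the observed counts, point to a structure of the samples, whose source was not tested.

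The second principal component held 12.4% of the variance and followed the male-biased mean over the 36 males with r = 0.86. In females there was a correlation of -0.39 between male-biased and macrophage genes (permutation test over 36 females, adjusted p = 0.0392; Spearman rho = -0.33, adjusted p = 0.0958), and male-biased means were 2.85 ± 0.26 in control and 2.93 ± 0.19 in misaligned females (log2 CPM, SD, n = 18).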
